A study of Mus musculus with 13 samples.

How the data were processed

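The deposited data were 2 tables of transposon and piRNA locus signal, from strand-specific RNA sequencing of mouse tumor lines: 8 libraries of B16 melanoma cells and 5 of KP lung adenocarcinoma cells. The B16 libraries were wild type (WT), Trp53 knockout, Tdg knockout and double knockout (DKO), 2 each. The KP libraries were WT (2) and Tdg knockout (3). Per the labels, RNA was extracted with TRIzol, depleted of ribosomal RNA and made into directional libraries. The submitters' processing notes name HISAT2, DESeq2 and the mm10 build without versions, and do not say which step made these tables. The deposited name gives piPipes mean signal, without a version or settings. Alignment settings, the treatment of reads that match several elements, and the number of reads per library are not given in the sources used here.

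The deposited values are named mean signal and were taken as read coverage per base of each element. The headers give a sense and an antisense column per library. The antisense values carried a minus sign, which was dropped. Each table held 2035 elements, of which 895 had any signal. After 6 exact duplicates were removed, 889 were analysed: 536 repeat consensus sequences and 353 piRNA loci. For 660 of 661 elements with 6 or more nonzero values (99.8%), all values in the 26 columns were whole multiples of a single step, so the coverage was not scaled to library size. The lowest values corresponded most often to 299 covered bases, or about 1 fragment. Related consensus sequences resemble each other and can hold the same reads, so neighbouring elements are not separate measurements. No column was left out.

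Each strand of an element was treated as 1 feature. Features with a mean coverage of at least 0.1 over the libraries of their table were kept: 1246 in B16 and 984 in KP. Values were analysed as log2 of coverage plus 0.1, the 10th percentile of nonzero values rounded to 1 digit, with limma 3.58.1 (lmFit, and eBayes with trend) in R 4.3.3. Both strands shared a fit, all groups of a table entered it, and each comparison was a two-sided contrast with Benjamini-Hochberg adjustment at 0.05. Because depth is unknown, the fit used the values as deposited. It was repeated with each library centred on its median, with quantile normalization, and, chosen after seeing the data, with each library scaled by its median ratio to the mean library over features with mean coverage of at least 1. A change is said to hold under all 4 scalings where it passed in the same direction in all of them. Residual degrees of freedom were 4 in B16 and 3 in KP.

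Element lists were fixed by name before the tables were opened and were tested per strand with limma's camera (inter-gene correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation and with fry. The name rules proved loose: the gammaretroviral list also took in elements of class ERV2 such as RLTR44E_LTR and RLTR46A2, and the list of MaLR and ERVL elements took in MERV1_LTR. The lists were used as fixed, and sets by the class given in each element name were added after seeing the data. The list of unmatched elements held the piRNA loci. Strand balance was fitted as log2 of sense over antisense coverage, and coverage shared by both strands as the lower of the 2. Summed signal was compared with a two-sided exact permutation test, whose smallest possible p is 0.333 for 2 against 2 and 0.100 for 2 against 3 libraries. Fold changes against a group with 0 in every library are given as lower bounds against a floor of 3 fragments per library, or left out where the other group lies under that floor. The closing section prints some fitted values against such a group and says so.

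Elements are named by a rule set beforehand. In the 3 comparisons of Tdg loss, these are the 10 largest rises and 10 largest falls among features that passed without overlap between groups (5 and 5 elsewhere), or up to 5 with the smallest p where fewer passed. In every comparison the best-covered sense member of 8 lists was added. Elements or strands named outside this rule for a comparison were chosen after their values were seen, also where a sentence does not say so.

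The fit was tested on simulated data with 200 changed features. Simulated noise was normal on the log2 scale and independent between features, with rises and falls in equal number. It had no shift common to a library and no reads shared between elements, unlike the data. The shares below are therefore not the error rates of the calls in the results. For DKO against Trp53 KO, changes of 4-fold, 8-fold and 16-fold were recovered in 27.5%, 63.0% and 74.0% of cases, and 2-fold changes in 0%. Of the calls 3.50%, 9.40% and 8.10% were false, above the nominal share at 8-fold and 16-fold. For KP, the recovered shares were 0% at 4-fold, 30.0% at 8-fold and 65.0% at 16-fold, with 9.10% and 3.00% of calls false at 8-fold and 16-fold. Over the repeat consensus sequences other than 7SL, coverage amounted to 259523 to 469929 fragments of 299 bases per B16 library and 49019 to 133044 per KP library. Log2 values of replicate libraries correlated at Pearson r = 0.903 for WT, 0.906 for Trp53 KO, 0.901 for Tdg KO and 0.863 for DKO. In KP, r was 0.829 for WT and 0.637 to 0.766 for Tdg KO. Alternatives covered the pseudocount, the filter, the scalings, a robust eBayes without trend, a block for replicate number, strands fitted apart, fits on the 2 groups of a contrast alone, and each library left out in turn. Leaving out the piRNA loci, and the 7SL consensus from summed signal, were added after seeing the data. Tdg and Trp53 transcripts, and transcripts that would mark other cell types, are not in the tables. Tables were read with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and plotted with matplotlib 3.10.9.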

Results

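Coverage of transposon and piRNA locus sequences was compared between B16 melanoma libraries of 4 genotypes and between KP lung adenocarcinoma libraries with and without Tdg. The 7SL consensus took 85.3% to 95.4% of all coverage in B16 and 93.3% to 99.1% in KP. Its entry is named as a pseudogene of Cavia, and the entries SINEB1_MU and SINEB2_MU below are named for Meriones. Sense coverage of 7SL reached 1198218 in DKO library 1 against 202366 in DKO library 2, and 3316360 in KP Tdg KO library 1 against 184730 and 306523 in the other libraries of that group. These libraries also had the highest coverage of the Rplp1 piRNA locus in their tables (4720 and 13796) and of the 7SL-related element PB1 (1157 and 2571). The p-values below measure only the spread between these libraries, since the labels do not say whether they come from separate cultures.

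**Figure D1:**
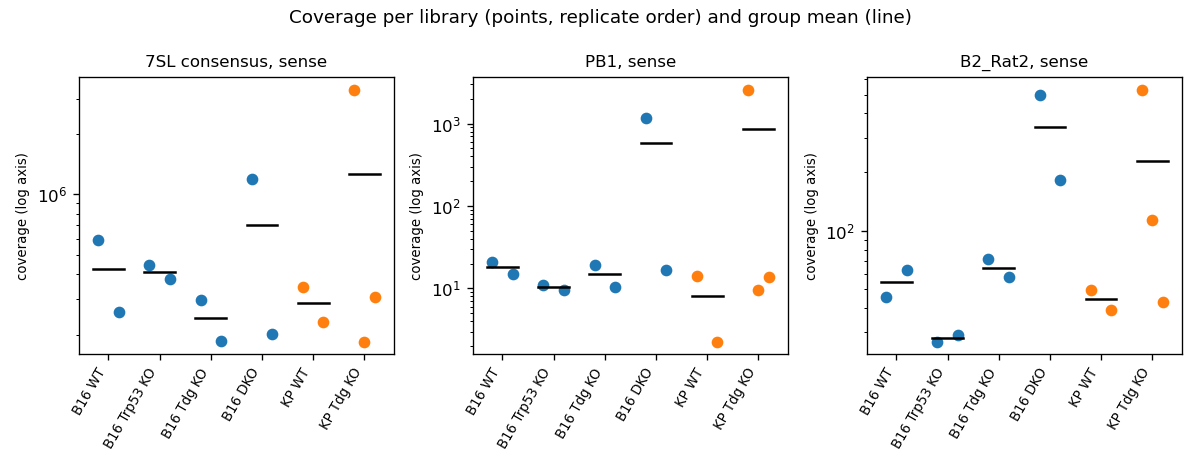
Sense coverage per base (log axes) of the 7SL consensus, PB1 and B2_Rat2 in each library (points, B16 blue and KP orange) with the mean of each group (lines). DKO library 1 and KP Tdg KO library 1 lie highest for 7SL, at 1198218 and 3316360.

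Loss of Tdg in Trp53 KO cells came with higher sense coverage of B1 and B2 SINEs, as single elements and as lists, but neither list passed with an estimated correlation (adjusted p = 0.555 and 0.922). B1_Mm and B2_Mm1a in sense were outside the naming rule here and chosen after their values were seen. B1_Mm sense coverage was 6.91 and 5.90 in the Trp53 KO libraries and 219 and 141 in the DKO libraries. B2_Mm1a sense coverage went from 4.89 and 7.08 to 237 and 57.2. That of B2_Rat2, named by the rule, went from 26.9 and 29.1 to 498 and 181 (log2 change 3.42, adjusted p = 0.0154 by limma). B1_Mur1 sense coverage was 0 in both Trp53 KO libraries and 8.27 and 15.7 in DKO, at least 1.99-fold higher. Of the 11 B1 elements measured in sense, 8 rose and 3 did not pass, with a median log2 change of 4.76 (4.70 with elements at 0 in a group set to their lower bounds). Of the 12 B2 elements, 11 rose, with a median of 3.96. In antisense, 8 of 12 B1 elements rose (median 4.10), and 5 of 13 B2 elements (median 2.71), with medians of 3.005 and 1.90 without DKO library 1. All 11 B1 and 12 B2 elements stayed higher in sense after median-ratio scaling, with 6 and 10 passing, and in antisense 8 B1 elements and 1 B2 element passed. PB1 did not pass (log2 change 3.74, adjusted p = 0.129), with 1157 in DKO library 1 and 16.6 in DKO library 2. Without Trp53 KO library 1, 0 of these elements passed on either strand (sense medians 4.87 and 3.38). Without Trp53 KO library 2, 5 B1 and 0 B2 elements passed in sense and 0 and 1 in antisense, and without DKO library 1, 4 and 5 in sense and 7 and 1 in antisense.

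Satellite coverage also changed in DKO against Trp53 KO. The antisense satellite features given here were outside the naming rule and chosen after their values were seen. Minor satellite (SATMIN) sense coverage fell from 343 and 132 in Trp53 KO to 12.3 and 24.3 in DKO (log2 change -3.61, adjusted p = 0.0163), while its antisense coverage rose from 4.11 and 13.1 to 194 and 154 (log2 change 4.54, adjusted p = 0.0197). Major satellite (GSAT_MM) sense coverage rose from 3.81 and 0 to 186 and 223 (log2 change 8.35, adjusted p = 0.0362), and its antisense coverage from 16.5 and 18.3 to 585 and 260 (log2 change 4.48, adjusted p = 0.0112). Of 4 satellites measured in sense, 1 rose and 1 fell, and of 3 in antisense, 2 rose. The SATMIN fall and the GSAT_MM antisense rise held under all 4 scalings. The GSAT_MM sense rise (adjusted p = 0.0904 by limma after median-ratio scaling) and the SATMIN antisense rise did not. Median-ratio scaling and median centring could only deepen the SATMIN fall (log2 change -5.00 and -5.66). The SATMIN sense fall did not pass without Trp53 KO library 1 (-2.92), Trp53 KO library 2 (-4.30) or DKO library 1 (-3.13), nor the GSAT_MM sense rise without any 1 library of the Trp53 KO, Tdg KO or DKO groups. Its log2 change was 10.99 without Trp53 KO library 1 and 5.70 without library 2, since 1 of these values is 0.

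**Figure D2:**
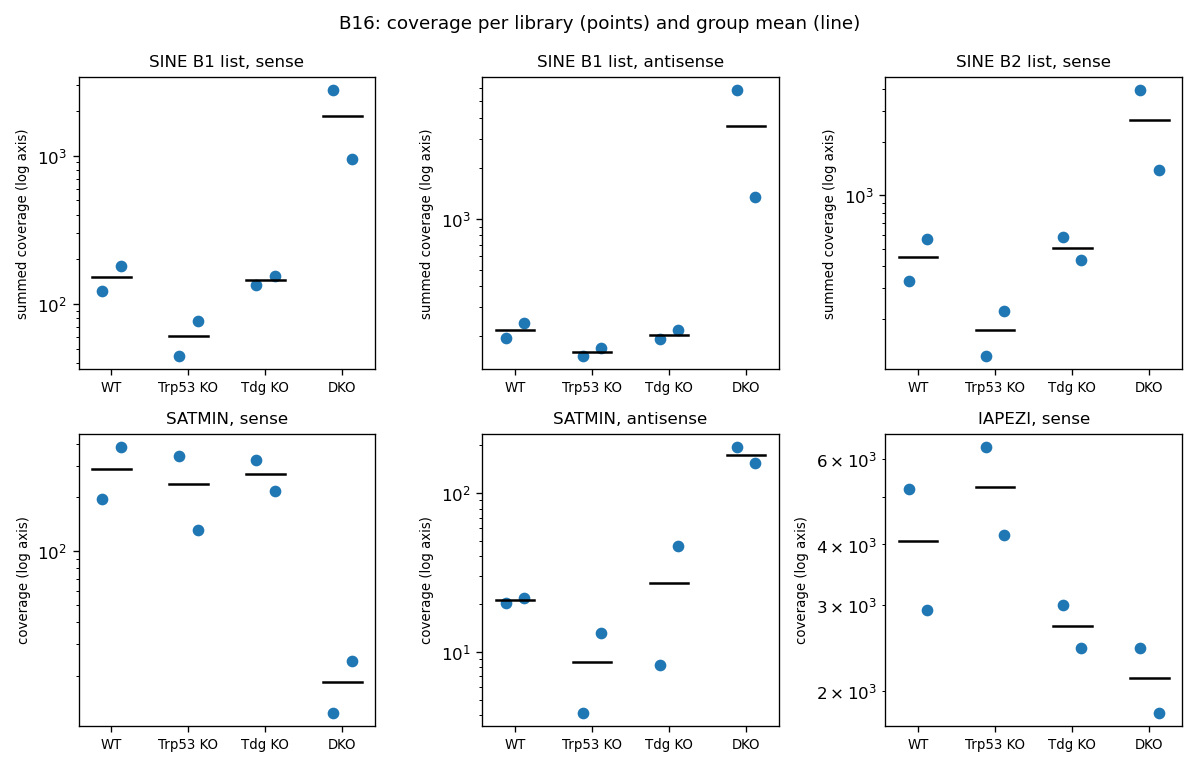
Coverage per base in each B16 library (points) with the group mean (lines), on log axes, summed over the members of the SINE lists in the top panels as marked. SATMIN sense coverage was 12.3 and 24.3 in the DKO libraries, below all 6 other libraries.

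Of 27 intracisternal A particle (IAP) elements in sense, 3 rose and 0 fell, and of 28 in antisense, 8 rose and 0 fell. After median-ratio scaling, 0 rose and 4 fell in sense, and 2 rose and 1 fell in antisense. IAPEZI sense coverage was 6322 and 4179 in Trp53 KO and 2448 and 1805 in DKO, a log2 change of -1.29 that did not pass (adjusted p = 0.0596) but did after median-ratio scaling (-2.67, adjusted p = 0.0248). The sense list had a median of 0.57 and a mean of 1.03, both above 0, although camera placed it below the other features, a rank lost with an estimated correlation (adjusted p = 0.922). The antisense list had a median of 1.28. MMETN, an early transposon element, had a log2 change of -1.13 (adjusted p = 0.118), and of -2.51 after median-ratio scaling (adjusted p = 0.0351). Neither the gammaretroviral element RLTR4I_MM (0.073, adjusted p = 0.888) nor L1MdF_IV (1.22, adjusted p = 0.0715) passed, and both were below 0 after median-ratio scaling (-1.31 and -0.16). MT2B2_LTR rose (1.45, adjusted p = 0.0340), but its change was 0.068 after median-ratio scaling and -0.60 after median centring.

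The other largest rises were in LTR, SINE and DNA transposon sequences that were absent or nearly so from Trp53 KO libraries. The lower bounds, which rest on the mean of both DKO libraries, were 6.67-fold for ORR1B antisense (27.2 and 7.33 in DKO), 3.69-fold for ERVB7_3-LTR_MM sense, 3.18-fold for RLTR30_MM antisense, 2.80-fold for RLTR27_MM antisense, 2.42-fold for URR1 sense and 1.77-fold for SINEB2_MU sense. RLTR10F sense (log2 change 6.58, adjusted p = 0.0447) and B2_Mm1a antisense (6.29, adjusted p = 0.0197) also rose, but without Trp53 KO library 1 or 2 the changes were 5.19 and 7.97 for RLTR10F and 4.29 and 8.30 for B2_Mm1a. Of these 8 rises only that of URR1 held under all 4 scalings. Without Trp53 KO library 1, 0 of them passed, and those of RLTR10F and ORR1B did not pass without any 1 Trp53 KO, Tdg KO or DKO library either. Apart from SATMIN, all falls were at piRNA loci. These 18 features carried 10 locus names, and 7 of them were overlapping loci of Ip6k1. pi-Ip6k1.1, pi-Ip6k1.3 and pi-Ip6k1.6 were at least 2.29-fold lower in DKO, pi-Ip6k1.4 and pi-Ip6k1.7 at least 2.60-fold, pi-Ip6k1.2 at least 2.61-fold and pi-Ing5.2 at least 1.09-fold. pi-Eif4ebp2.2 fell by 2.44 log2 units (adjusted p = 0.0396 by limma), and pi-Rab11fip4.2 was at 0 in both DKO libraries and under the floor for a fold in Trp53 KO. The Ip6k1 bounds given rest on 13.8 to 15.7 fragments over both Trp53 KO libraries. Trp53 KO was also above WT at pi-Ing5.2 (at least 1.09-fold) and pi-Ip6k1.2 (log2 change 1.79), without passing. No piRNA locus fell past the threshold in DKO against WT or against Tdg KO, so these falls are relative to Trp53 KO.

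Of 1246 features, 368 rose (169 sense, 199 antisense) and 19 fell (17 sense, 2 antisense) in DKO against Trp53 KO (limma, adjusted). With only these 2 groups in the fit 0 passed, so the calls rest on the spread shared with the WT and Tdg KO groups. The median absolute log2 difference between replicates was 0.81 in DKO and 0.42 to 0.52 in the other B16 groups. The shared spread may thus be too small for DKO. With a block for replicate number 298 rose and 24 fell. Of the 368 rises, 160 were at piRNA loci. The median log2 change over all features was 1.67 (1.18 with lower bounds), and 90.3% of changes were above 0. Median-ratio scaling took out a shift of 1.38 and left 57.9% above 0, and median centring took out 2.05 and left 40.8%. Under all 4 scalings, 23 rises (14 sense, 9 antisense) and 19 falls held. Median-ratio scaling and median centring could only deepen the falls, so passing under them adds no support for the falls. Of these 23, 12 were members of the B1 and B2 lists. Chosen after their values were seen, the other sense rises were BGLII, ERVB4_2B-LTR_MM, LTRVL30, RLTRETN_MM, RMER17B and URR1. The counts depended on each library compared: without Trp53 KO library 1 they were 2 and 0, without Trp53 KO library 2 they were 15 and 0, without DKO library 1 they were 133 and 7, and without DKO library 2 they were 364 and 9. With each of these left out in all scalings, 0, 4, 5 and 27 of the 42 changes still held, in that order, and all 42 kept their direction each time.

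Among the lists, B1 sense (adjusted p = 0.00278), B1 antisense (0.0151) and B2 sense (0.00101) ranked above the other features by camera, and IAP sense (0.00278) and the unmatched elements in sense (0.00199) below them. With an estimated correlation no list passed: adjusted p = 0.555 for B1 sense and 0.922 for the other 4. By fry, which does not compare a list with other features and therefore takes in the broad rise, 21 of 26 lists passed (smallest adjusted p = 0.00119). By the same test 13 passed against Tdg KO, 2 against WT, 15 in the interaction and 0 in each other comparison (smallest adjusted p = 0.155, in KP). After median-ratio scaling B1 sense, B1 antisense and B2 sense still ranked above (medians 3.38, 2.72 and 2.57), and B2 antisense did too (median 1.33), which it had not without scaling (adjusted p = 0.177). IAP sense stayed below (median -0.82, adjusted p = 0.0121), and young LINE-1 antisense ranked below the others (median -0.78), which it had not without scaling. Of 38 MaLR and ERVL elements in antisense, 19 rose, and 21 with adjustment over the list alone. After median-ratio scaling 2 of them rose. Of 30 young LINE-1 elements in sense, 3 rose, 27 with adjustment over the list alone, and 0 after median-ratio scaling.

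**Figure D3:**
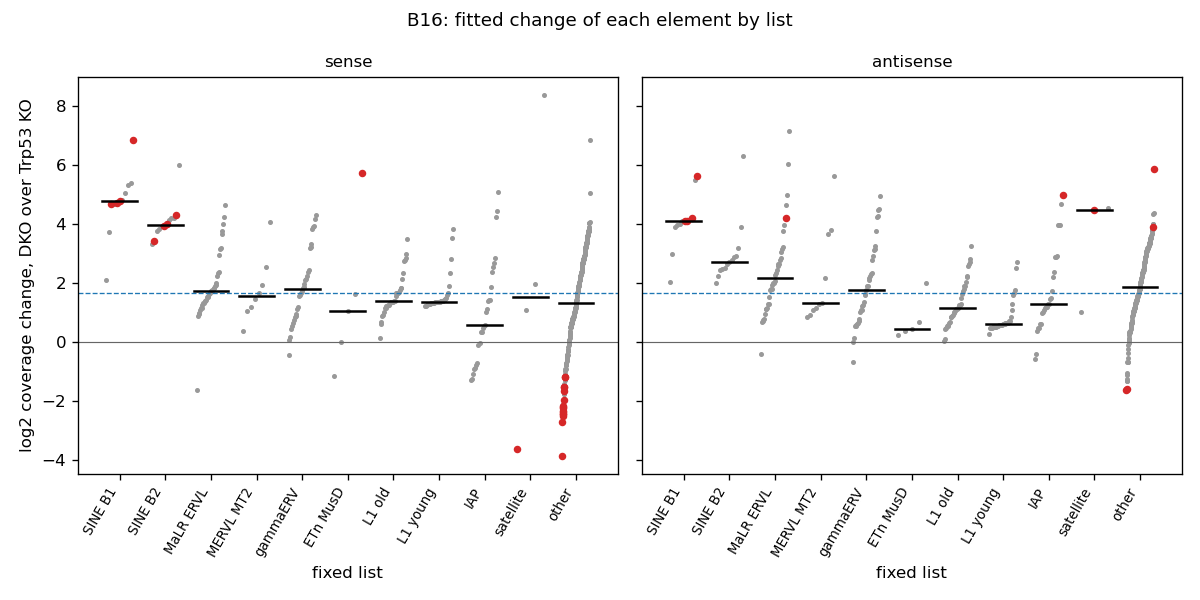
Fitted log2 change of each feature in DKO against Trp53 KO by list and strand (points), with red points for changes that held under all 4 scalings, list medians (black bars) and the median over all features, 1.67 (dashed line). The B1 and B2 medians in sense, 4.76 and 3.96, lie above the dashed line, and the IAP median, 0.57, lies below it.

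The ratio of sense to antisense coverage shifted toward antisense at 12 elements and toward sense at 1 in DKO against Trp53 KO. None of the 13 calls remained with robust eBayes, with the replicate block or without the piRNA loci. They became 1 with the pseudocount multiplied by 10 and 23 with it divided by 10. The pseudocount weighs on the ratio where a strand is near 0, but the cause of these moves was not tested. The shift toward sense was at RLTR19A2, which was at 0 on both strands in Trp53 KO, as were RNLTR10A and RLTR12E among the shifts toward antisense. These also included pi-Elk4.1 (log2 change of the strand ratio -3.56, adjusted p = 0.0374) and pi-Phf20.2 (-2.89, adjusted p = 0.0374), all chosen after their values were seen, and 7 of the 12 were the Ip6k1 loci. SATMIN shifted most (-8.15) but did not pass (adjusted p = 0.0609). The lower of the 2 strands rose at 194 of 495 elements and fell at 0. These were spread over 14 lists, with 92 unmatched elements, 30 further RLTR elements, 12 MaLR and ERVL, 11 gammaretroviral, 10 older LINE-1, 8 IAP, 8 B1 and 7 B2 elements, and included GSAT_MM (8.35, adjusted p = 0.0300) and RLTRETN_MM (adjusted p = 0.00743), which was at 0 in sense in both Trp53 KO libraries. The lower strand of GSAT_MM was its sense strand in every B16 library, so its value repeats the sense change given above. One of its Trp53 KO values is 0, which makes that change depend on the pseudocount. Over the lower strand of all elements, 27 rose and 2 fell with median-ratio scaling, and 4 rose and 2 fell with median centring. Without DKO library 1, 25 strand shifts passed, and 38 without DKO library 2, but 0 without any 1 library of the other groups. The 194 rises were 64 without Trp53 KO library 1, 88 without Trp53 KO library 2 and 72 without DKO library 1. Neither measure passed at any element after loss of Tdg or Trp53 alone in B16 or of Tdg in KP. Before adjustment (limma), the strand ratio rose and fell at 19 and 13, 31 and 8, and 8 and 17 elements in these comparisons, and the lower strand at 7 and 5, 0 and 34, and 10 and 1. After median-ratio scaling the lower strand rose and fell at 10 and 3, 4 and 17, and 4 and 2.

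Loss of Tdg in Trp53 wild-type B16 cells changed no feature past the threshold. None of the best-covered elements passed, where the same number of libraries recovered 0% of 2-fold changes simulated for DKO against Trp53 KO: IAPEZI (log2 change -0.53), MMETN (-0.59), RLTR4I_MM (-0.11), MT2B2_LTR (-0.18), L1MdF_IV (0.12), PB1 (-0.34), B2_Rat2 (0.26) and SATMIN (-0.048), each with an adjusted p of 1.00. The features with the smallest p were sparsely covered. Sense coverage of LTRIS4A was 0 in both WT libraries and 6.15 and 3.76 in Tdg KO, at least 2.62-fold higher, and RMER17B sense was at least 1.19-fold higher, without passing (adjusted p = 0.235 for both). RLTR20B4_MM and IAPEY5_LTR antisense and LTRVL30 sense were seen only in Tdg KO, and RLTR20A3_MM and ORR1D1_LTR antisense and RLTR44E_LTR, MT2B and RLTR46A2 sense only in WT, all under the floor for a fold. Without adjustment, 15 features rose and 27 fell (limma), or 21 and 17 after median-ratio scaling. With adjustment 6 passed when either DKO library was left out of the fit, and 1 without WT library 2. Young LINE-1 elements ranked higher in sense (30 elements, median 0.18, camera adjusted p = 0.0193) and lower in antisense (32 elements, median -0.32, adjusted p = 0.000998), and older LINE-1 antisense ranked lower (median -0.34, adjusted p = 0.000998). The sense rank held after median-ratio scaling (adjusted p = 0.000913), as did the older antisense rank (0.0374), the young antisense rank did not (0.152), and with an estimated correlation none passed (adjusted p = 0.996).

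Loss of Trp53 alone also changed no feature past the threshold, with 16 rises and 65 falls before adjustment (limma) and a median log2 change of -0.41. The counts were 27 and 35 after median-ratio scaling (median 0.072), 35 and 31 after median centring and 29 and 36 after quantile normalization. With adjustment, 12 passed without DKO library 1 in the fit, 13 without DKO library 2 and 1 without Trp53 KO library 1. B2 SINEs in sense were lower as a group (12 elements, median -1.51, camera adjusted p = 0.000357), but no list of this comparison passed with an estimated correlation (adjusted p = 0.938), and 0 of the 12 passed singly. B2_Rat2 was at 45.6 and 63.0 in WT and 26.9 and 29.1 in Trp53 KO (log2 change -0.93, adjusted p = 0.704). The other best-covered elements did not pass: IAPEZI (0.39), MMETN (0.17), RLTR4I_MM (0.28), MT2B2_LTR (-0.77), L1MdF_IV (-0.61), PB1 (-0.79) and SATMIN (-0.36). Among the smallest p, pi-Ing5.2 sense was at least 1.09-fold higher and RLTR41B antisense at least 1.83-fold lower. RLTR6B_Mm antisense was lower (-2.20, adjusted p = 0.255), and SINEB1_MU antisense (3.75, adjusted p = 0.377) and pi-Ip6k1.2 sense (1.79, adjusted p = 0.401) were higher. A piRNA locus without a gene name and LTRIS4A, both in sense, were seen only in Trp53 KO, and MERV1_LTR and RLTR20A3_MM antisense and RLTRETN_MM sense only in WT, under the floor for a fold. The lists of gammaretroviral elements and of MaLR and ERVL elements ranked lower in antisense (medians -1.31 and -0.62, adjusted p = 0.0104 and 0.0252), and young LINE-1 on both strands (-0.42 in antisense, -0.63 in sense). IAP sense (median 0.00, mean -0.17) and unmatched sense features (median -0.31) ranked higher by camera although neither list was above 0. These ranks were also lost with an estimated correlation, and after median-ratio scaling young LINE-1 no longer ranked lower (adjusted p = 0.966 in antisense and 0.0520 in sense).

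The comparisons of DKO with Tdg KO and with WT share the DKO libraries. SATMIN sense coverage fell by 3.93 log2 units against Tdg KO (adjusted p = 0.0430 by limma) and by 3.98 against WT (adjusted p = 0.0387). Median-ratio scaling and median centring could only deepen these falls. Chosen after its values were seen, GSAT_MM rose in antisense by 2.87 (adjusted p = 0.0429 by limma) and 3.31 (adjusted p = 0.0348), without holding under all 4 scalings. Its sense change did not pass in either (6.27, adjusted p = 0.112, and 8.14, adjusted p = 0.0701). SINEB1_MU antisense (115 and 34.9 in DKO) was at least 11.1-fold higher than in Tdg KO and rose by 8.12 log2 units over WT (adjusted p = 0.0286), or by 6.93 without WT library 1 and 9.31 without WT library 2, and passed against WT only without DKO library 2 when a library was left out. B1_Mur2 sense was at least 2.94-fold and B1_Mur1 sense at least 1.99-fold higher in both, and RMER15 sense at least 4.47-fold higher than in WT. B1_Mur2 antisense rose over Tdg KO (5.60, adjusted p = 0.0430, but 4.56 without DKO library 1 and 6.64 without DKO library 2, the only library without which it passed), and SINEB2_MU antisense rose in both but lay under the floor for a fold. In all, 38 features rose and 1 fell against Tdg KO, and 51 rose and 1 fell against WT (limma, adjusted). In both comparisons 0 passed with a block for replicate number or with the 2 groups of the contrast fitted alone. Under all 4 scalings 2 rises (B1_Mur1 sense and SINEB1_MU antisense) and the fall of SATMIN held against Tdg KO, and 3 rises (also SINEB2_MU antisense) and the fall of SATMIN against WT. Against Tdg KO, 0 of these held without any 1 Tdg KO library or DKO library 1, and against WT 0 held without any 1 WT library or DKO library 1. The SATMIN fall passed only without DKO library 2 when a B16 library was left out of the unscaled fit. The counts of 39 and 52 were 0 without either Trp53 KO library, 81 and 76 without DKO library 1, and 300 and 268 without DKO library 2. B1 in both strands and B2 in sense ranked above the other features in both comparisons (medians 3.28, 4.06 and 2.20 against Tdg KO, and 3.21, 3.74 and 2.45 against WT), without passing with an estimated correlation (smallest adjusted p = 0.369 and 0.331). Best-covered elements other than SATMIN did not pass against Tdg KO, among them IAPEZI (-0.37), MMETN (-0.37), RLTR4I_MM (0.47), MT2B2_LTR (0.87), L1MdF_IV (0.49), PB1 (3.28) and B2_Rat2 (2.22, adjusted p = 0.0501). Against WT, B2_Rat2 rose (2.48, adjusted p = 0.0469), and IAPEZI (-0.90), MMETN (-0.96), RLTR4I_MM (0.36), MT2B2_LTR (0.69), L1MdF_IV (0.61) and PB1 (2.95) did not pass. The falls closest to the threshold were ZP3AR antisense (-1.44, adjusted p = 0.0699), pi-Ccdc117.1 (at least 1.69-fold), pi-Cbl.2 (-1.47) and RLTR1_MM (-2.59) against Tdg KO, and pi-Rab11fip4.1 (-2.04, adjusted p = 0.0518), pi-Eif4ebp2.2 (-2.51), pi-Phf20.2 (-1.15) and pi-Rab11fip4.2 against WT.

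Whether the effect of Tdg loss differed with Trp53 status was tested as an interaction, and 0 features passed (smallest adjusted p = 0.0662, limma), with 427 above and 10 below 0 before adjustment. That imbalance came with the unscaled fit: the counts were 99 and 70 after median-ratio scaling, 75 and 82 after quantile normalization, and 53 and 169 after median centring. Without DKO library 1, 88 passed, without DKO library 2, 304, and without Trp53 KO library 1, 1. The smallest p belonged to B1_Mm sense (5.15), B1_Mur1 sense, BGLII sense, RLTR44E_LTR sense and RLTR20A3_MM antisense, each with an adjusted p of 0.0662. Below 0 were pi-Ing5.2, pi-Ip6k1.1, pi-Ip6k1.2, pi-Ip6k1.4 and SATMIN (-3.56), each at 0.0757. Except for B1_Mm and SATMIN, these features were at 0 in every library of at least 1 group, so the pseudocount sets the size of their interaction and none is given. B2_Rat2 (3.16) was also at 0.0757, and IAPEZI (-0.76), MMETN (-0.54), RLTR4I_MM (0.18), MT2B2_LTR (1.64), L1MdF_IV (1.10) and PB1 (4.08) were further off. As lists, B1 sense (median 4.86), B1 antisense (4.12) and B2 sense (3.70) ranked above the other features (camera adjusted p = 0.00446, 0.00446 and 0.00294) and did so after median-ratio scaling, but with an estimated correlation the adjusted p was 0.562 for B1 sense and 0.985 for the other 2. Of 6 other lists that passed without it (adjusted p = 0.0260 to 0.0488), young LINE-1 antisense ranked above the others without scaling and below them after median-ratio scaling.

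In KP cells, Tdg loss changed no feature past the threshold. VL30 (MMVL30) sense coverage was 1140 and 1337 in WT and 3714, 4091 and 3169 in Tdg KO, without overlap (log2 change 1.56, adjusted p = 0.777 by limma). Its change was 0.88 after median-ratio scaling and -0.37 after quantile normalization. B1 and B2 SINEs in sense ranked higher as lists (13 and 12 elements, medians 1.73 and 1.51, camera adjusted p = 0.0240 for both), with 0 members passing, but neither list passed with an estimated correlation (adjusted p = 0.906), nor did any other list. The coverage was uneven: B2_Rat2 sense was 530, 114 and 43.0 in Tdg KO against 49.8 and 39.3 in WT (log2 change 1.63), and the highest value was in the library with the highest 7SL coverage, library 1. IAP and older LINE-1 elements in sense ranked lower (medians -0.31 and 0.14, adjusted p = 0.00908 and 0.00575). Their means, 0.17 and 0.048, were above 0. ETn and MusD antisense and young LINE-1 antisense ranked higher (medians 0.96 and 0.88, adjusted p = 0.0310 and 0.0269). After median-ratio scaling the young LINE-1 list did not (0.108).

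Before adjustment, 44 KP features rose and 4 fell of 984 (limma, smallest adjusted p = 0.223), but 15 and 12 after median-ratio scaling, 14 and 10 after median centring and 15 and 13 after quantile normalization. Without scaling they were 68 and 6 without Tdg KO library 1, 80 and 12 without library 3, 34 and 12 without WT library 1, and 42 and 15 without WT library 2. RLTRETN_MM antisense was at least 1.20-fold and RMER6C antisense at least 1.32-fold higher, and LX5 sense at least 1.49-fold lower. IAPEY3C_LTR sense and LTRIAPEY and BGLII_Mus antisense were seen only in Tdg KO, and RLTR19B_MM, L1_Rat3_3end and SQR1_MM sense only in WT, under the floor for a fold. LX4 sense was lower (-2.21, adjusted p = 0.777). None of the other best-covered elements passed: IAPEY4_I (-1.33), MMETN (-0.36), MT2B2_LTR (0.079), L1MdF_IV (0.54), PB1 (3.60) and MMSAT4 (0.82). The median log2 change was 0.75 (0.42 with lower bounds), and 79.5% of changes were above 0, or 55.0% after median-ratio scaling.

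Summed coverage followed the 7SL consensus. The two-sided exact permutation test cannot reach 0.05 with these numbers of libraries, so its p-values decide nothing here. The log2 ratio of summed coverage was -0.78 for Tdg KO against WT in B16 (exact p = 0.667), 0.75 for DKO against Trp53 KO (exact p = 1.00), -0.045 for Trp53 KO against WT (exact p = 1.00) and 2.13 for KP Tdg KO against WT (exact p = 0.900). Without KP Tdg KO library 1 the last ratio was -0.18, without DKO library 1 the ratio for DKO was -0.91, and for Trp53 KO it was 0.62 without WT library 1 and 0.068 without Trp53 KO library 2. The changes after Tdg loss in Trp53 KO B16 cells and in KP cells were weakly alike over 960 features (Pearson r = 0.203, Spearman rho = 0.227). They had the same sign for 80.5% of features, or 56.0% after median-ratio scaling, and r was -0.0404 without KP Tdg KO library 1 and 0.346 without library 3. The changes after Tdg loss in Trp53 wild-type and Trp53 KO B16 cells correlated at r = 0.176 (rho = 0.238, 1246 features, 46.1% of the same sign, or 62.0% after median-ratio scaling), and at r = 0.0278 without WT library 1. Features share reads, so no p is given for these correlations.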

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

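All tests of explanations in this part were chosen after the results were seen. The 6 results that follow stand out because all libraries moved one way in B16 and the opposite way in KP, and none of these differences was tested. They were picked from 57 comparisons of a named element between the cell lines. All but MMVL30 had been named for a small p in KP. Since 90.3% of changes in DKO against Trp53 KO were above 0, elements named for a fall in KP were likely to lie opposite. RMER6C antisense had a log2 change of -0.46 after Tdg loss in Trp53 wild-type B16 and of 4.13 in KP, a difference of -4.60. MMVL30 sense stood at -0.15 and 1.56, a difference of -1.71, but its B16 change was 0.0068 after median-ratio scaling and its KP change was -0.37 after quantile normalization. For DKO against Trp53 KO in B16, LX5 sense stood at 2.12 and at -3.33 in KP (difference 5.45), RLTR19B_MM sense at 1.79 and -2.74 (4.53), L1_Rat3_3end sense at 1.85 and -2.78 (4.62), and LX4 sense at 1.76 and -2.21 (3.97). After median centring the B16 changes of RLTR19B_MM (-0.26), L1_Rat3_3end (-0.21) and LX4 (-0.29) lay below 0, and after quantile normalization that of LX5 (-0.38) did too. KP coverage was 0 in every WT library for RMER6C, and in every Tdg KO library for LX5, RLTR19B_MM and L1_Rat3_3end, so these fitted values depend on the pseudocount.

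In DKO against Trp53 KO, 368 features rose, with a median log2 change of 1.67 over all features. A difference in depth as the whole cause would move weakly and strongly covered features alike. The median log2 change at coverage of 1 to 10 instead exceeded that at 100 or more by 0.72 to 1.49 in all 4 library pairings. The log2 ratio of coverage summed over the weakly covered features, which needs no pseudocount, was 1.24 to 2.02. Also, 42 changes (23 rises and 19 falls) passed under all 4 scalings, but not without Trp53 KO library 1. Median-ratio scaling and median centring took 1.38 and 2.05 off every change, so they could only deepen the falls. Both DKO libraries were at 0 for 9 falls, and both Trp53 KO libraries for 9 rises. Genomic DNA as the whole cause would add coverage to both strands alike. The strands instead differed by more than 2-fold in 48.3% and 33.1% of 151 risen elements with at least 30 added fragments in both DKO libraries. The antisense share of coverage without 7SL was 36.6% and 39.1% in DKO and 21.7% to 32.0% in the other B16 libraries. DNA as part of the cause would also move this share upward. A common factor as large as the 0.68 to 0.85 at high coverage stays open, and for the 345 rises that did not pass under all scalings, of which 32 passed after median-ratio scaling (median log2 change 1.67, median standard error 0.65), depth and a change in the cells cannot be told apart because depth is not in the tables. For 65 of the 151 elements the added coverage lay within 2-fold between strands in both DKO libraries, so DNA and transcription of both strands cannot be told apart there, and the genotype itself stays open as an untested explanation.

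B1 and B2 sense coverage was higher in DKO than in Trp53 KO libraries, with list medians of 4.76 and 3.96. Reads of 7SL RNA assigned to B1 would keep the ratio of the 2 constant, but the summed coverage of the 11 B1 elements as a share of 7SL coverage was at least 11.3-fold higher in DKO, and 7.48-fold without the 2 PB1 elements. Genomic DNA as the whole cause would add to both strands of B2 alike. The added coverage was instead higher in sense for 12 of 12 elements in both DKO libraries, with median log2 ratios of 1.61 and 1.99. DNA as part of the B2 rise stays open, since summed B2 antisense coverage also rose. It was 77.0 and 175 in Trp53 KO and 1364 and 443 in DKO. A property of DKO library 1 would end with its removal, but without it and with median-ratio scaling the medians were 2.07 for B2 and 3.24 for B1, although fewer elements passed (1 of 12 and 3 of 11). Genomic DNA remains open for B1, whose added coverage was higher in antisense (median log2 ratios of sense over antisense -2.67 and -0.29, the second near-equal), as do reads of longer transcripts that carry SINE copies, which the tables cannot show, and the genotype.

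In DKO, SATMIN sense coverage fell while its antisense share of coverage was 94.0% and 86.4%, and 18 piRNA locus features fell. A loss of strand specificity would turn reads of other RNAs to the wrong strand, but at most 0.0352% of 7SL coverage was antisense in the DKO libraries, and genomic DNA would add to SATMIN sense coverage, whose higher DKO value was 18.4% of the lower Trp53 KO value. Reads of IAP RNA counted at piRNA loci are a candidate explanation for the 5 falling features with coverage of 100 or more: their coverage stayed at 8.82% to 15.8% of IAPEZI sense coverage in all 8 B16 libraries, within 1.40-fold for each, while IAPEZI itself varied 3.50-fold. The 13 other falling piRNA features were not covered by this test. For SATMIN the genotype stays open, as a hypothesis found and tested on the same data that the fit without Trp53 KO library 1, Trp53 KO library 2 or DKO library 1 did not carry past the threshold (-2.92, -4.30 and -3.13).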

How the results depend on the processing

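The scaling of libraries by their median ratio, the fits without the piRNA loci, the sets by class, the sums without 7SL and the calls with each library left out under every scaling were chosen after seeing the data, and the other alternatives before. The 25 results that answer a comparison were recomputed in 410 combinations of result and setting. Of these, 284 counted as unchanged, 116 moved and 10 changed sign. A count was taken as unchanged within 1.5-fold, and summed signal wherever its sign held, whatever its size. The 132 named results (an element in a comparison) were recomputed in 2494 combinations of result and setting. Of these, 2074 kept their sign and their side of the threshold, 274 fell short of it with the same sign, 72 newly passed and 74 changed sign. Of 35 named results past the threshold, 34 never changed sign (MT2B2_LTR in DKO against Trp53 KO was the exception), and they still passed in 32 cases with the pseudocount multiplied by 10, 29 with it divided by 10, 33 without a filter, 31 with robust eBayes, 19 with the replicate block, 34 with strands fitted apart, 21 with median centring, 22 with quantile normalization and 23 with median-ratio scaling. Of those still tested, 20 of 27 passed with the filter at 10 times the pseudocount and 23 of 26 without the piRNA loci. None of the 35 passed when the groups of a contrast were fitted alone, which leaves 2 residual degrees of freedom, or without Trp53 KO library 1, and 2 passed without Trp53 KO library 2, 13 without DKO library 1, 22 without DKO library 2, 18 without either Tdg KO library and 24 without either WT library. A left-out library leaves 1 library in its group (2 for Tdg KO in KP), which is then assumed to vary like the other groups. The depth of the libraries is not in the tables, so a common factor between groups cannot be separated from a change of all elements, and only differences between well-covered elements and ratios of well-covered strands escape it, since the pseudocount makes ratios near 0 depend on depth. In KP, with 49019 to 133044 fragments per library in repeats other than 7SL, simulated 16-fold changes were recovered in 65.0% of cases and 4-fold changes in 0%, and whether coverage, replicate spread or the number of libraries sets this was not tested. A count-based model was not run because the values are not counts, and quantile normalization was not run for summed signal because it fixes the totals.

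Scaling subtracts a shift by construction, fits on fewer groups or with a block have fewer residual degrees of freedom, and fewer features are tested without the piRNA loci or with the higher filter. For the other changes below the cause was not tested. Libraries are named by group and replicate. Features changed in DKO against Trp53 KO numbered 387, and 136 with median centring, 90 with quantile normalization, 105 with median-ratio scaling, 135 without the piRNA loci, 0 with the groups of the contrast alone, 2 to 418 with 1 library left out (2 without Trp53 KO 1, 15 without Trp53 KO 2, 140 without DKO 1). Features changed in Trp53 KO against WT numbered 0, but 3 with the pseudocount divided by 10, 6 with the groups of the contrast alone, 0 to 13 with 1 library left out (1 without Trp53 KO 1, 12 without DKO 1, 13 without DKO 2). Features changed in DKO against Tdg KO numbered 39, and 157 with the pseudocount multiplied by 10, 15 with the filter multiplied by 10, 4 with median centring, 21 with quantile normalization, 146 with robust eBayes, 0 with the replicate block and with the groups of the contrast alone, 6 with median-ratio scaling, 24 without the piRNA loci, 112 with strands fitted apart, 0 to 300 with 1 library left out (5 without WT 1, 6 without WT 2, 0 without Trp53 KO 1 or Trp53 KO 2 or Tdg KO 1 or Tdg KO 2, 81 without DKO 1, 300 without DKO 2). Features changed in DKO against WT numbered 52, and 15 with the filter multiplied by 10, 7 with median centring and with median-ratio scaling, 27 with quantile normalization and without the piRNA loci, 105 with robust eBayes, 0 with the replicate block and with the groups of the contrast alone, 0 to 268 with 1 library left out (0 without WT 1 or Trp53 KO 1 or Trp53 KO 2 or Tdg KO 1 or Tdg KO 2, 1 without WT 2, 268 without DKO 2). Features changed in the interaction numbered 0, but 7 with the pseudocount divided by 10 and with robust eBayes, 1 with the filter multiplied by 10, 4 with strands fitted apart, 0 to 304 with 1 library left out (1 without Trp53 KO 1, 88 without DKO 1, 304 without DKO 2). Features changed in Tdg KO against WT numbered 0, but 0 to 6 with 1 library left out (1 without WT 2, 6 without DKO 1 or DKO 2). Strand ratios changed in Tdg KO against WT numbered 0, but 5 with the pseudocount divided by 10, 0 to 7 with 1 library left out (2 without Tdg KO 2, 7 without DKO 1, 3 without DKO 2). Strand ratios changed in DKO against Trp53 KO numbered 13, and 1 with the pseudocount multiplied by 10 and with the filter multiplied by 10, 23 with the pseudocount divided by 10, 0 with robust eBayes, with the replicate block and without the piRNA loci, 0 to 38 with 1 library left out (0 without WT 1 or WT 2 or Trp53 KO 1 or Trp53 KO 2 or Tdg KO 1 or Tdg KO 2, 25 without DKO 1, 38 without DKO 2). Strand ratios changed in Trp53 KO against WT numbered 0, but 12 with the pseudocount divided by 10, 0 to 7 with 1 library left out (7 without DKO 1, 4 without DKO 2). Elements changed on the lower strand in DKO against Trp53 KO numbered 194, and 6 with median centring and with quantile normalization, 29 with median-ratio scaling, 48 without the piRNA loci, 64 to 250 with 1 library left out (64 without Trp53 KO 1, 88 without Trp53 KO 2, 72 without DKO 1). Elements changed on the lower strand in Trp53 KO against WT numbered 0, but 3 with the pseudocount divided by 10, 0 to 5 with 1 library left out (5 without Trp53 KO 1, 1 without Trp53 KO 2). Elements changed on the lower strand in KP numbered 0, but 1 with the pseudocount divided by 10. Elements changed on the lower strand in Tdg KO against WT numbered 0, but 0 to 2 with 1 library left out (1 without WT 2, 2 without DKO 1 or DKO 2). Lists called in Tdg KO against WT numbered 3, and 6 with the filter multiplied by 10, 1 with median centring, with quantile normalization and with robust eBayes, 0 with an estimated correlation, 2 to 6 with 1 library left out (6 without WT 2). Lists called in DKO against Trp53 KO numbered 5, and 8 with median centring and with quantile normalization, 0 with an estimated correlation, 2 to 6 with 1 library left out (2 without DKO 2). Lists called in Trp53 KO against WT numbered 7, and 3 with robust eBayes, 0 with an estimated correlation, 3 to 9 with 1 library left out (3 without WT 2). Lists called in KP numbered 6, and 2 with robust eBayes, 0 with an estimated correlation, 3 with sets by class, 1 to 8 with 1 library left out (1 without WT 1, 3 without WT 2 or Tdg KO 1, 2 without Tdg KO 2).

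Summed signal changed sign for DKO against Trp53 KO (0.75) with median centring (-1.49) and median-ratio scaling (-0.75), and ranged from -0.91 to 1.497 with 1 library left out (below 0 without DKO 1). For Trp53 KO against WT (-0.045) it was 0.031 without 7SL, 0.55 with median centring, 0.36 with median-ratio scaling, and -0.50 to 0.62 with 1 library left out (above 0 without WT 1 or Trp53 KO 2). For KP (2.13) it ranged from -0.18 to 2.64 (below 0 without Tdg KO 1). The correlation of Tdg effects in DKO and KP (0.203) was 0.357 with the pseudocount multiplied by 10, 0.346 with the replicate block, and -0.0404 to 0.346 with 1 library left out (lowest without KP Tdg KO 1, highest without KP Tdg KO 3). That of Tdg KO and DKO (0.176) ranged from 0.0278 to 0.246 (without WT 1 and WT 2). In KP, the replicate block gives Tdg KO library 3 a level of its own, so its results come close to those without that library. With median centring, the sign changed for RLTR4I_MM (0.017) and SATMIN (0.079) in Tdg KO against WT, RLTR4I_MM (-1.98), MT2B2_LTR (-0.60) and L1MdF_IV (-0.83) in DKO against Trp53 KO, L1MdF_IV (0.065) and SATMIN (0.31) in Trp53 KO against WT, RLTR4I_MM (-1.03), MT2B2_LTR (-0.63) and L1MdF_IV (-1.01) in DKO against Tdg KO, RLTR4I_MM (-1.02), MT2B2_LTR (-0.69) and L1MdF_IV (-0.76) in DKO against WT, RLTR4I_MM (-1.99), MT2B2_LTR (-0.54) and L1MdF_IV (-1.08) in the interaction, MT2B2_LTR (-0.61) and L1MdF_IV (-0.15) in KP. With quantile normalization, the sign changed for RLTR4I_MM (0.34) and SATMIN (0.23) in Tdg KO against WT, L1MdF_IV (-0.15) in DKO against Trp53 KO, RLTR4I_MM (-0.44) in Trp53 KO against WT, MT2B2_LTR (-0.063) and L1MdF_IV (-0.71) in DKO against Tdg KO, MT2B2_LTR (-0.20) and L1MdF_IV (-0.38) in DKO against WT, L1MdF_IV (-0.48) in the interaction, MMVL30 (-0.37), MT2B2_LTR (-0.82) and MMSAT4 (-0.049) in KP. RLTR4I_MM in DKO against Tdg KO went to 0, which was counted as a change of sign. IAPEZI in Trp53 KO against WT went to 0 within rounding, which was not. With median-ratio scaling, the sign changed for RLTR4I_MM (0.046) and SATMIN (0.11) in Tdg KO against WT, RLTR4I_MM (-1.31) and L1MdF_IV (-0.16) in DKO against Trp53 KO, SATMIN (0.12) in Trp53 KO against WT, RLTR4I_MM (-0.59), MT2B2_LTR (-0.19) and L1MdF_IV (-0.57) in DKO against Tdg KO, RLTR4I_MM (-0.54), MT2B2_LTR (-0.21) and L1MdF_IV (-0.29) in DKO against WT, RLTR4I_MM (-1.36) and L1MdF_IV (-0.44) in the interaction, MT2B2_LTR (-0.60) and L1MdF_IV (-0.14) in KP. With the replicate block, the sign changed for MT2B2_LTR (-0.88) and L1MdF_IV (-0.13) in KP. With 1 library left out, the sign changed without the library named after each range. In Tdg KO against WT, this held for RLTR4I_MM (-0.32 to 0.10, without Tdg KO 2), SATMIN (-0.53 to 0.43, without WT 2 or Tdg KO 2), MT2B2_LTR (-0.58 to 0.22, without WT 2 or Tdg KO 2), L1MdF_IV (-0.42 to 0.67, without WT 1 or Tdg KO 1) and PB1 (-0.77 to 0.10, without Tdg KO 2). In DKO against Trp53 KO, this held for RLTR4I_MM (-0.37 to 0.52, without Trp53 KO 2 or DKO 1). In Trp53 KO against WT, this held for RLTR4I_MM (-0.16 to 0.73, without Trp53 KO 1), SATMIN (-1.05 to 0.33, without WT 2 or Trp53 KO 2), IAPEZI (-0.018 to 0.80, without WT 2) and MMETN (-0.26 to 0.60, without WT 2 or Trp53 KO 1). In the interaction, this held for RLTR4I_MM (-0.26 to 0.63, without Trp53 KO 2 or Tdg KO 2 or DKO 1). In KP, this held for MT2B2_LTR (-0.88 to 0.86, without WT 1 or Tdg KO 3), L1MdF_IV (-0.13 to 1.13, without Tdg KO 3) and MMETN (-1.32 to 0.68, without WT 2 or Tdg KO 1). In DKO against Tdg KO, this held for MMETN (-0.85 to 0.11, without Tdg KO 1). In DKO against WT, this held for PB1 (-0.11 to 6.01, without DKO 1).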

Other observations

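The elements in this part were chosen after their values were seen. MMERGLN, an endogenous gammaretrovirus, had higher mean sense coverage in both groups without Tdg than in their counterparts with Tdg in B16. Sense coverage of its LTR was 72.0 and 163 in WT, 206 and 158 in Tdg KO, 47.8 and 31.2 in Trp53 KO, and 414 and 311 in DKO. WT and Tdg KO overlapped. The LTR rose in DKO against Trp53 KO (log2 change 3.21, adjusted p = 0.0154 by limma, and 1.83, adjusted p = 0.0265, after median-ratio scaling), but its change of 1.16 did not pass after median centring. The internal part MMERGLN_I had sense coverage of 270 and 476 in WT, 557 and 507 in Tdg KO, 232 and 183 in Trp53 KO, and 751 and 1067 in DKO (2.12, adjusted p = 0.0163), and did not pass after median-ratio scaling (0.73, adjusted p = 0.219). Sense coverage of MMERGLN_LTR stayed below 10 in every KP library. With a DKO or Trp53 KO library left out, the log2 change of MMERGLN_LTR in sense stayed between 2.91 and 3.52 and passed only without DKO library 2 (adjusted p = 0.0243). That of MMERGLN_I passed without either DKO library (adjusted p = 0.0484 and 0.0404) and not without either Trp53 KO library (0.0706 and 0.0668).

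In DKO against Trp53 KO, neither of 2 IAP sequences passed in sense without scaling, and their difference was not tested. Sense coverage of IAPLTR1_Mm_LTR lay between 197 and 229 in the 6 other B16 libraries and was 881 and 316 in DKO (log2 change 1.39, adjusted p = 0.0612), but its change was 0.0071 after median-ratio scaling. That of the internal sequence IAPLTR1a_I_MM went from 4902 and 3114 in Trp53 KO to 1983 and 1353 in DKO (-1.25, adjusted p = 0.0704, and -2.64, adjusted p = 0.0265, after median-ratio scaling). The satellite-class element IMPB_01 had sense coverage of 222 in Tdg KO library 1 and 832 in DKO library 1, and at most 2.70 in the other B16 libraries.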
